A study of Mus musculus with 12 samples.

How the data were processed

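The deposited values are gene-level intensities of the Mouse Transcriptome Array 1.0, summarised with SST-RMA per the file headers, and the submitters' processing notes name RMA without a version. The series-wide file and the series matrix hold the same 72688 probe sets and 12 arrays, with 0 differing values. The intensities run from 3.272572 to 994483.4, so they are linear, and their log2 was taken here. The plan of tests had taken the deposited values to be on the log2 scale already, and the tests themselves were kept. No further normalization was applied.

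Per the labels, the cells are OT-I splenocytes primed for 4 days with N4 or Y3, with or without corticosteroid in RPMI1640 medium with serum and glutamine. Also per the labels, RNA came from RNeasy Plus Mini columns and was hybridised as biotin-labelled single-stranded DNA. The labels number the arrays of each group 1 to 3 as biological replicates. The name and dose of the corticosteroid and the array's genome build are not given in the sources used here.

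Of the probe sets, 6732 are controls, 40122 carry 1 gene symbol, 1 carries several and 25833 non-control probe sets carry none. The unit tested was a gene. Where a symbol had several probe sets (461 genes), the brightest over all arrays was taken, which gave 39462 genes. There was no filter on brightness. The highest value of 23 antigenomic background probe sets on any array, 6.40 log2, marks the background level, and on the other 11 arrays their highest values lay between 5.41 and 6.15.

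Tests used R 4.3.3 with limma 3.58.1 and data.table in version 1.17.8, and the figures Python 3.11.15 with matplotlib 3.10.9. Limma fitted all 12 arrays with 4 group means and 5 contrasts: corticosteroid in N4-primed cells, corticosteroid in Y3-primed cells, Y3 against N4 without and with corticosteroid, and the interaction. Benjamini-Hochberg adjustment ran over the genes of each contrast, with a threshold of 0.05. The 23 gene lists (656 genes, of which 645 were measured and 11 were not) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. The tests, the lists, the genes always named and the first set of alternatives were written before the data were examined.

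The pairing of same-numbered arrays rests on the replicate numbers of the labels, and no source used here states that they share a mouse or a culture. It was checked by correlating deviations from the group means across genes between same-numbered arrays of different groups. All 18 correlations were above the limit of 0.1, from 0.114 to 0.815. The deviations of a group sum to 0, so the 18 are not separate checks. Across peptides they were -0.0458 to 0.0825 without replicate 1, under the limit. Without replicate 2 or 3 the lowest across peptides were 0.433 and 0.51. The check across peptides therefore rests on replicate 1. The planned fit had no block, and a fit with the replicate number as a block was planned as its alternative. After the data were seen, 4 other fits were added: a block for each peptide and replicate number (6 pairs), the block with only the 2 groups of a contrast, the replicate number as a random block, and the block with the 6 pairs as a random block. A contrast for the corticosteroid effect averaged over both peptides was also added then. For the peptide comparisons the calls without a block come first, because in the self-test the block gave more false calls.

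Genes named in the text follow a rule: per contrast the 6 largest rises and 6 largest falls past the threshold whose groups do not overlap, without provisional symbols, immunoglobulin or T cell receptor segments and predicted names, the 3 members of each list past the threshold with the largest change, and 10 genes always (among them Tsc22d3, Fkbp5, Nr3c1, Cpt1a, Gzmb, Ifng, Il7r, Cd8a and Bcl2). Some genes that the rule names are not reported here. It was repeated on the fit with the replicate block and on the within-peptide fit, there with every pair changed the same way in place of groups that do not overlap, a repeat added after the data were seen. For genes named as the largest rises or falls, the same direction in every pair therefore follows from the rule and is no separate support. Genes taken from a list's top members are left out where the list is only summarised.

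A self-test ran the fits on simulated data of 39462 genes with known changes, 100 genes by a log2 of 1 and 100 by a log2 of 2. The simulated arrays shared an effect within each peptide and replicate number, as the within-peptide fit assumes. For corticosteroid and the interaction, 30 further genes were shifted by a log2 of 0.5, and calls on them count among the calls but not as false. For corticosteroid in Y3-primed cells, the fit without a block found 61 and 91 of them (0 of 158 calls false), the replicate block 72 and 96 (1 of 182) and the within-peptide fit 82 and 98 (10 of 207). For the interaction, the within-peptide fit found 69 and 92 (4 of 167). For Y3 against N4 without corticosteroid, the numbers were 63 and 91 without a block (4 of 158), 75 and 95 with it (70 of 240) and 1 and 72 with only the 2 groups and a block (1 of 74). For Y3 against N4 with corticosteroid, they were 58 and 91 (1 of 150), 75 and 96 (86 of 257) and 5 and 80 (2 of 87). The list of these 30 shifted genes had a camera adjusted p = 1.88e-78 without a block and 3.05e-57 in the within-peptide fit, or 1.1e-06 and 0.00232 with an estimated correlation, and 0 of 23 other lists were called. Apart from replicate-number effects, equal in all groups, the simulated noise was independent between genes. These list results therefore do not show how camera fares where the genes of a list vary together.

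Each result was recomputed with 1 choice changed at a time: the fits above, only the 2 groups of a contrast, the genes brighter than the median, all non-control probe sets, the mean of a gene's probe sets, quantile normalization, median centring, a trend and robust spread model, array weights, the values of the other table, a 2-fold minimum change, and each array left out in turn. Leaving out each replicate number in all groups and the repeats of these alternatives under the blocks were added after the data were seen.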

Results

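Gene expression was measured on 12 mouse transcriptome arrays of OT-I cells, CD8 T cells with a transgenic receptor for an ovalbumin peptide, labelled as splenocytes. The cells were primed in culture for 4 days with N4, the ovalbumin peptide itself, or with Y3, an altered peptide ligand of the same receptor. Each peptide was used with and without a corticosteroid whose name and dose are not given in the sources used here. The 4 groups held 3 arrays each, a number that limits the precision of every value. Array medians over 39462 genes lay between 5.02 and 5.16 log2 intensity. The mean of 14216 genes lay above 6.40, the highest value of the antigenomic background probe sets, and that of 25246 genes at or below it. Cd8a, a chain of the CD8 co-receptor, stood at 15.90 ± 0.0525 log2 intensity after N4 and 16.38 ± 0.568 after Y3 (SD, n = 3).

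The replicate number separated the arrays more than either treatment did. It accounted for 42.8% of the total variance, the peptide for 25.39% and the corticosteroid for 5.117%. Of the 12 arrays, 10 correlated best across genes with the same-numbered array of the other treatment and the same peptide. The other 2, both of Y3-primed cells given corticosteroid, correlated best with each other. Same-numbered arrays deviated from their group means together, with correlations across genes of 0.524 to 0.815 within a peptide and 0.114 to 0.712 across peptides. Without replicate 1 the correlations were 0.328 to 0.757 within a peptide and -0.0458 to 0.0825 across peptides. Results are therefore given from the fit without a block and from fits that use the replicate number, which the labels give and call biological.

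**Figure D1:**
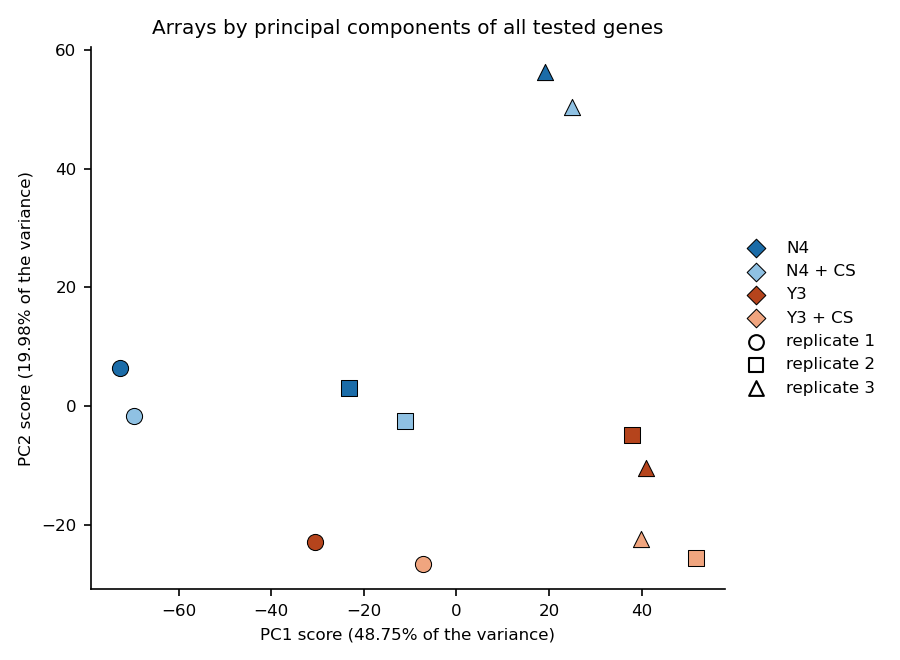
Scores of the 12 arrays on the first and second principal components of 39462 genes (48.75% and 19.98% of the variance), coloured by group (CS, corticosteroid) and shaped by replicate number. Of the variance of PC1, 63.32% lies between replicate numbers and 29.17% between peptides, and of that of PC2 25.17% and 50.77%.

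Corticosteroid changed little that could be called in N4-primed cells. Amica1, an adhesion molecule with a costimulatory role in T cells, rose from 10.82 ± 0.274 to 12.06 ± 0.257 log2 intensity (SD, n = 3), a difference of 1.24 found in 3 of 3 same-numbered pairs. It was the only gene called by limma with Benjamini-Hochberg adjustment, with adjusted p = 0.014 with the replicate number as a block and 0.0259 with the pairs blocked within each peptide. Ifng, the effector cytokine interferon gamma, stood at 11.08 ± 3.52 without and 8.39 ± 3.98 with corticosteroid. Its difference of -2.68, negative in 3 of 3 pairs, missed the threshold (within-peptide limma adjusted p = 0.0504). Tsc22d3 and Fkbp5, which the glucocorticoid receptor is known to induce, differed by 1.07 and 0.52, positive in 3 of 3 pairs each (within-peptide limma adjusted p = 0.345 and 0.708).

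Of the other genes chosen in advance in N4-primed cells, the differences were 0.29 for the interleukin-7 receptor gene Il7r, 0.18 for Cpt1a, which brings fatty acids into mitochondria, 0.034 for Cd8a and 0.0058 for the survival gene Bcl2. They were -0.074 for Nr3c1, which encodes the glucocorticoid receptor, and -0.17 for the granzyme gene Gzmb. All had limma adjusted p between 0.611 and 0.999 in the within-peptide fit. The fit without a block, planned in advance, called 0 genes with limma. In it 749 had an unadjusted p under 0.05, against 1973 that chance would give. The counts at an unadjusted p under 0.05 were 1312 with the replicate block and 2613 with pairs within each peptide. Only the 2 groups with a block gave 0 genes (2726 unadjusted, adjusted p = 0.182 for Amica1), the replicate number as a random block 0 (1169) and the block with random pairs 1 (2155). In the within-peptide fit 1 gene passed without N4 replicate 1 or N4_CS replicate 1. With any other array left out (N4 or N4_CS replicate 2 or 3, or any Y3 or Y3_CS array), 0 genes passed.

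Among the 23 gene lists, camera called 4 as lower in N4-primed cells given corticosteroid. Proteostasis and stress response genes had a median difference of -0.195 over 26 measured members (adjusted p = 1.55e-05), with pair medians from -0.294 to -0.16 and 13 of 26 members lower in every pair. Cytokines and chemokines had a median of -0.115 over 34 members (adjusted p = 0.00735), glycolysis genes of -0.138 over 26 (adjusted p = 0.0173) and B cell markers of -0.041 over 21 (adjusted p = 0.00397). The pair medians were -0.169 to -0.0709, -0.312 to 0.00959 and -0.061 to -0.0339. Each of the 4 had an adjusted p = 0.909 with an estimated correlation. The glycolysis call was lost without replicate 1 (adjusted p = 0.604) or replicate 2 (0.224) and the B cell call without replicate 1 (0.127). Those of cytokines and of B cell markers were lost among genes brighter than the median (0.228 each). The replicate block called 8 lists and the within-peptide fit 9. Among the 9 were sterol and fatty acid synthesis genes (median -0.19, adjusted p = 1.75e-10, or adjusted p = 0.154 with an estimated correlation) and interferon-stimulated genes (median 0.121, adjusted p = 1.33e-05, or adjusted p = 0.55 with an estimated correlation). It also called oxidative phosphorylation (median -0.0793, adjusted p = 6.11e-05), T cell activation (-0.164, 0.00115) and CD4 and regulatory T cell genes (-0.11, 0.046), with adjusted p = 0.387, 0.271 and 0.387 with an estimated correlation. Adjusted over the list alone, that fit called 8 cytokine genes, 5 proteostasis genes and 4 sterol and fatty acid synthesis genes lower, and over all genes none of them. Glucocorticoid receptor targets had a median of 0.0122 and a mean of -0.0358, with the test pointing down (adjusted p = 0.927), and effector differentiation genes a median of -0.0232 and a mean of 0.0749 (0.927). The other lists had medians between -0.0563 and 0.0176, with adjusted p between 0.271 and 0.972.

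In Y3-primed cells corticosteroid raised Gzma, Tsc22d3, Slamf6 and Il7r and lowered Ifng, Scd1 and Asns. Gzma, which encodes granzyme A, rose from 10.74 ± 2.13 to 14.83 ± 1.66 log2 intensity (SD, n = 3), and Tsc22d3 from 8.23 ± 0.412 to 9.83 ± 0.627. Slamf6, a receptor of progenitor-like CD8 T cells, rose by 1.09 and Il7r by 1.02. Ifng fell from 7.998 ± 1.73 to 5.77 ± 1.28, a level below the background maximum of 6.40, and Scd1, a desaturase of fatty acid synthesis, from 13.28 ± 1.42 to 11.47 ± 1.77. Asns, which encodes asparagine synthetase, fell from 11.30 ± 0.413 to 9.69 ± 0.641.

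These calls come from limma with each peptide's same-numbered arrays as pairs, a fit added after the data were seen, which called 119 of 39462 genes (41 higher, 78 lower). The differences ± SE in that fit were 4.09 ± 0.544 for Gzma (adjusted p = 0.0481), 1.60 ± 0.226 for Tsc22d3 (0.0491), 1.09 ± 0.0955 for Slamf6 (0.0205) and 1.02 ± 0.0883 for Il7r (0.0205). They were -2.23 ± 0.213 for Ifng (0.0259), -1.81 ± 0.138 for Scd1 (0.0205) and -1.61 ± 0.17 for Asns (0.0325). All 7 changed in the same direction in 3 of 3 pairs, and did so after N4 too, where the fit called none of them. After N4, Gzma stood at 12.16, 12.53 and 6.24 without and 14.09, 17.23 and 9.65 with corticosteroid. Slamf6 stood there at 7.60, 8.98 and 11.14 without and 8.40, 10.04 and 12.02 with it. The calls therefore do not make these changes particular to Y3. Also called, in 3 of 3 pairs each, were rises of the phosphodiesterase gene Pde2a by 1.70, Zyg11b by 1.24 and Serpina3f by 1.24 (adjusted p = 0.0481, 0.0491 and 0.0445). The mean of Serpina3f over all arrays lay under the background maximum, and the Serpina3 genes are close paralogs, so its probes may not separate them. The amino acid transporter gene Slc7a5 fell by 1.48, the granzyme gene Gzmc by 1.38 and the inhibitory receptor gene Havcr2 by 1.23 (adjusted p = 0.0481, 0.0205 and 0.0205). After N4 the pairs of Slc7a5 and of Havcr2 went both ways. The difference of the Gzmc group means, which ignores the pairs, turned to 0.54 without Y3 replicate 1 and to 0.22 without Y3_CS replicate 3.

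Of the genes chosen in advance, 3 passed that fit in Y3-primed cells (Tsc22d3, Ifng and Il7r). The other differences were 0.85 for Fkbp5, 0.70 for Bcl2, 0.45 for Cpt1a, 0.22 for Cd8a and 0.00027 for Nr3c1, and -0.47 for Gzmb, with limma adjusted p between 0.0874 (Bcl2, positive in 3 of 3 pairs) and 0.999. The planned fit without a block called 0 genes, with 1259 at an unadjusted p under 0.05, and gave each gene named here an adjusted p = 1. The replicate block across peptides called 0 (2649 unadjusted, smallest adjusted p 0.136), only the 2 groups with a block 0 (4517, smallest 0.102), the replicate number as a random block 0 (2017) and the block with random pairs 11 (4169). Leaving out any array lowered the count of 119: to 37 without replicate 1 of N4 or N4_CS, 4 without replicate 2 and 0 without replicate 3 of either, and to 1 without replicate 1 of Y3 or Y3_CS and 0 without replicate 2 or 3 of either. In simulated data of this comparison, with 100 genes changed 2-fold, 100 changed 4-fold and 30 shifted by a log2 of 0.5 among 39462, the within-peptide fit found 82% of the first and 98% of the second. Of its 207 calls, 10 fell on genes without a simulated change. The fit without a block found 61% and 91%, with 0 such calls among 158. The simulation built in the pairs that the within-peptide fit assumes, so it cannot show whether that fit suits the real arrays.

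**Figure D2:**
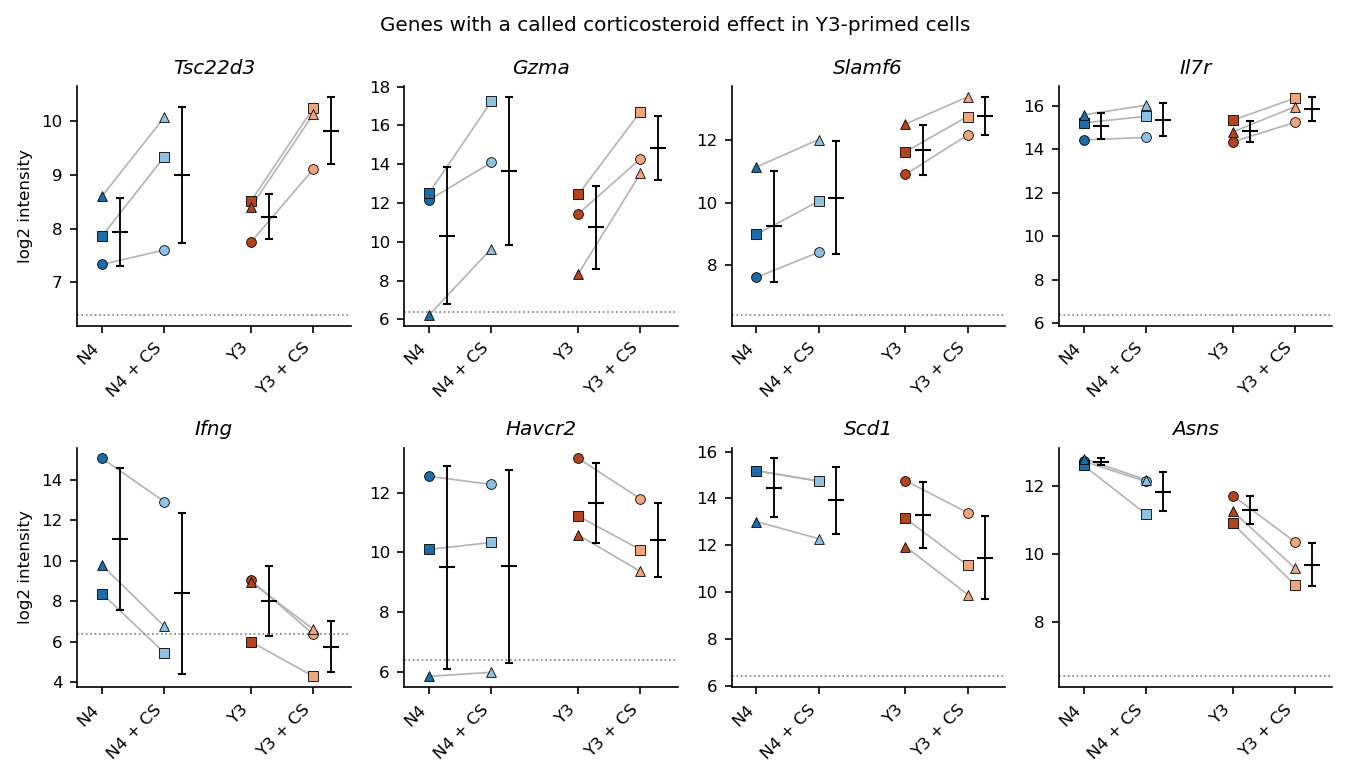
Log2 intensity of 8 genes on each array by group (CS, corticosteroid), with shapes for replicate numbers 1 (circle), 2 (square) and 3 (triangle), lines joining same-numbered arrays of a peptide, bars for mean ± SD (n = 3) and a dotted line at the background maximum of 6.40. Each of the 8 keeps its direction in the 3 Y3 pairs, while levels differ widely between replicate numbers.

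Sterol and fatty acid synthesis genes had the largest median fall of the called lists in Y3-primed cells given corticosteroid, -0.582 over 30 measured members (camera adjusted p = 2.17e-07, or adjusted p = 0.909 with an estimated correlation). In the within-peptide fit the adjusted p was 9.26e-32, or 0.0407 with an estimated correlation. The list's median was -0.659, -0.552 and -0.489 in the 3 pairs, and 26 of 30 members were lower in every pair. Of its members 11 fell over all genes and 24 adjusted over the list alone, among them Fdps, an enzyme of isoprenoid synthesis, by 1.12 (adjusted p = 0.0205) and the desaturase gene Fads2 by 1.15 (0.0224), in 3 of 3 pairs each. Proteostasis and stress response genes had a median of -0.479 (camera adjusted p = 5.92e-08, or adjusted p = 0.397 with an estimated correlation), pair medians of -0.572 to -0.325 and 18 of 26 members lower in every pair. In the within-peptide fit 2 of them fell over all genes, Asns and the mitochondrial folate enzyme gene Mthfd2 (by 0.96, adjusted p = 0.0385, 3 of 3 pairs), and 16 fell adjusted over the list alone.

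Camera also called 3 other lists as lower in Y3-primed cells given corticosteroid. Oxidative phosphorylation genes had a median of -0.166 over 53 members (adjusted p = 2.17e-07, or adjusted p = 0.909 with an estimated correlation), with pair medians of -0.208 to -0.113. Glycolysis genes had a median of -0.278 (adjusted p = 4.47e-07, or adjusted p = 0.397 with an estimated correlation), with pair medians of -0.617 to -0.0762. B cell markers had a median of -0.0576 (adjusted p = 0.0143, or adjusted p = 0.909 with an estimated correlation, and 0.0831 without replicate 3), with pair medians of -0.169 to -0.0286. Adjusted over the list alone, the within-peptide fit called 12 oxidative phosphorylation, 8 glycolysis and 3 B cell genes lower. Over all genes it called 0, 0 and 1 lower, the 1 being Cd74, a chaperone of class II antigen presentation, which fell by 0.76 (adjusted p = 0.0489, 3 of 3 pairs).

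Lists tied to steroid action and to fatty acid use had small medians in Y3-primed cells, and members of the first went both ways. Glucocorticoid receptor targets had a median of 0.0378 over 33 members (camera adjusted p = 0.74). In the within-peptide fit Tsc22d3 rose and the metallothionein gene Mt2 fell by 0.58 (adjusted p = 0.0491, 3 of 3 pairs), with 5 higher and 7 lower adjusted over the list alone. Fatty acid oxidation genes had a median of -0.0723 over 44 members, with camera adjusted p = 0.075 without a block and 0.019 in the within-peptide fit (adjusted p = 0.726 with an estimated correlation). Naive and memory T cell genes had a median of 0.107 over 31 members (adjusted p = 0.403, and 0.0256 in the within-peptide fit, or adjusted p = 0.748 with an estimated correlation). The pair medians were 0.28, 0.062 and -0.16, so the third pair went the other way. Of these genes 2 were called higher over all genes, Il7r and Slamf6, and 4 adjusted over the list alone. Proliferation genes had a median of 0.195 over 47 members (adjusted p = 0.232, and 0.000136 in the within-peptide fit, or adjusted p = 0.748 with an estimated correlation). Their pair medians ran from -0.16 to 0.795. Inhibitory receptors and exhaustion genes had a median of 0.0888 over 26 members (adjusted p = 0.109, 0.0706 in the within-peptide fit, and 0.0368 with the replicate block, or adjusted p = 0.626 with an estimated correlation), with Havcr2 the 1 called member.

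Effector differentiation genes in Y3-primed cells had a median of 0.00412 over 34 members (adjusted p = 0.981), with the test pointing down. Of these Gzma rose and Gzmc and the interleukin-2 receptor gene Il2ra fell, Il2ra by 0.78 (adjusted p = 0.0263, 3 of 3 pairs). Cytokines and chemokines had a median of -0.0455 (adjusted p = 0.792, Ifng lower) and T cell activation genes of -0.0415 (adjusted p = 0.468, Il2ra and Slc7a5 lower). The medians were -0.0184 for apoptosis regulators (29 members), 0.012 for migration, adhesion and residency genes (31, with the test pointing down), -0.00484 for T cell identity genes (21) and 0.0583 for interferon-stimulated genes (37), with camera adjusted p of 0.74, 0.843, 0.601 and 0.636. The within-peptide fit called the interferon-stimulated genes higher (adjusted p = 0.0455, or adjusted p = 0.748 with an estimated correlation), with pair medians of 0.11, 0.28 and -0.11. Among markers of other cells, the medians were 0.0194 for myeloid and dendritic cells (30), 0.000584 for granulocytes and mast cells (21), -0.0255 for NK cells (16), -0.0117 for CD4 and regulatory T cells (13), 0.042 for erythroid cells and platelets (17) and 0.0248 for stromal and endothelial cells (15). Their adjusted p lay between 0.232 and 0.981. The mast cell gene Cpa3 fell by 0.77 at a mean under the background maximum (within-peptide adjusted p = 0.0385, 3 of 3 pairs).

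Without corticosteroid, Y3-primed cells had more Ly6c2 and Tle4 transcript than N4-primed cells and less of Basp1 and Ndrg2. Ly6c2, a surface antigen of memory-type CD8 T cells, was at 10.48 ± 0.836 log2 intensity after N4 and 14.62 ± 0.646 after Y3 (SD, n = 3), a difference of 4.14 (limma adjusted p = 0.0268). The transcriptional corepressor gene Tle4 rose by 1.82 (0.0171), the histamine receptor gene Hrh2 by 1.29 (0.0268) and the exonuclease gene Xrn2 by 0.59 (0.035). Basp1, which encodes a membrane-bound signalling protein, was lower, at 7.75 ± 0.152 after Y3 against 9.63 ± 0.359 after N4, a difference of -1.87 (0.0171). Ndrg2 fell by 1.87 (0.0252), the proline synthesis gene Pycr1 by 1.22 (0.0252) and Slc4a11 by 0.72 (0.0171), the last with a mean under the background maximum. Each of these genes differed in the same direction in 3 of 3 same-numbered pairs. The rule for named genes takes only groups that do not overlap, so this follows from the choice.

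Limma without a block called 12 genes in this comparison (6 higher, 6 lower, with 3380 at an unadjusted p under 0.05). Only the 2 groups without a block gave 0. With the replicate block 1160 genes passed (670 higher, 490 lower), with only the 2 groups and a block 297 (187 higher, 110 lower), with the replicate number as a random block 159 and with the block and random pairs 994. In simulated data of this comparison, 4 of 158 calls were false without a block, 70 of 240 with the replicate block and 1 of 74 with only the 2 groups and a block. The 12 genes were all among the 1160, and 7 of them among the 297. Without a block, the count was 2, 8 and 0 without N4 replicate 1, 2 and 3, 20, 8 and 23 without N4_CS replicate 1, 2 and 3, 26, 0 and 0 without Y3 replicate 1, 2 and 3, and 18, 9 and 0 without Y3_CS replicate 1, 2 and 3. The count of 1160 became 428, 243 and 502 without N4 replicate 1, 2 and 3 and 516, 576 and 294 without Y3 replicate 1, 2 and 3.

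Interferon-stimulated genes were higher after Y3 without corticosteroid, with a median difference of 1.09 over 37 members (camera adjusted p = 1.39e-23, or adjusted p = 0.16 with an estimated correlation), pair medians of 0.967, 0.597 and 1.49 and 34 of 37 members higher in every pair. Limma without a block called 2 of them higher over all genes, Ifit3 by 0.96 and Oas2 by 0.83 (adjusted p = 0.0268 each, 3 of 3 pairs), both with means under the background maximum, so the sizes of their rises are uncertain. Adjusted over the list alone 21 were higher and 1 lower. With the replicate block 20 were called higher over all genes, among them the transcription factor gene Irf7 by 2.22 (adjusted p = 0.0116) and the nucleic acid sensor gene Zbp1 by 2.13 (0.00291), in 3 of 3 pairs each. Rises called with the block included related interferon-inducible genes of the PYHIN family: Pydc3 by 4.80 (0.00325), Pydc4 by 4.64 (0.00217), Pyhin1 by 3.67 (0.00449) and Ifi203 by 3.63 (0.000576), in 3 of 3 pairs each. Probes for such close paralogs may bind more than 1 of them, so which member rose is uncertain.

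Genes of naive and memory T cells had a median of 0.411 after Y3 without corticosteroid (camera adjusted p = 0.000159, or adjusted p = 0.415 with an estimated correlation), with pair medians of 0.285 to 0.668. Limma called Ly6c2 alone over all genes and 3 higher and 1 lower adjusted over the list alone. With the replicate block 8 were higher and 1 lower, among them the transcription factor gene Tcf7 by 2.87 (adjusted p = 0.043) and Slamf6 by 2.44 (0.0201), in 3 of 3 pairs each. Bcl2 was the lower gene, at -2.02 (adjusted p = 0.00498 with the block, 0.325 without, 3 of 3 pairs). T cell identity genes had a median of 0.38 (camera adjusted p = 1.95e-05, or adjusted p = 0.373 with an estimated correlation), with pair medians of 0.178 to 0.419. None of them passed limma over all genes or over the list alone without a block, and 4 passed over all genes with it, among them Cd8b1 by 0.79 (adjusted p = 0.00918, 3 of 3 pairs).

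Lower after Y3 without corticosteroid were proteostasis and stress response genes (median -0.573, camera adjusted p = 1.96e-08, pair medians -0.673 to -0.472) and glycolysis genes (-0.372, 2.45e-07, -0.616 to -0.302), each with adjusted p = 0.16 with an estimated correlation. Also lower were proliferation genes (-0.625, 2.9e-05, -1.19 to -0.177), T cell activation genes (-0.303, 0.000458, -0.498 to -0.153) and cytokines and chemokines (-0.101, 0.00163, -0.281 to -0.0188), with adjusted p = 0.691, 0.415 and 0.347 with an estimated correlation. CD4 and regulatory T cell markers (-0.0757, 0.00637, -0.205 to 0.0289) and sterol and fatty acid synthesis genes (-0.271, 0.0281, -1.12 to 0.59) were also called, with adjusted p = 0.16 and 0.792 with an estimated correlation. Without a block none of these genes was called over all genes. Adjusted over the list alone 8 proteostasis, 1 glycolysis, 6 activation, 3 cytokine and 2 CD4 list genes were lower, and 1 activation gene was higher. The replicate block called 12 proteostasis, 8 activation, 5 cytokine and 3 glycolysis genes lower over all genes, among them Asns by 1.42 (adjusted p = 0.0112), the costimulatory receptor gene Tnfrsf4 by 2.06 (0.00567), the interleukin gene Il24 by 5.42 (0.0135) and the glycolytic enzyme gene Pfkm by 1.06 (0.0121), in 3 of 3 pairs each. Il24 stood at 4.81 after Y3, under the background maximum, so the size of its fall is uncertain.

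Several of these list calls rested on 1 replicate number. The proliferation call was lost without replicate 2 (adjusted p = 0.612), the CD4 list call without replicate 3 (0.0757) and the sterol call without replicate 1 (0.0862) or replicate 2 (0.612, where its direction turned) and among genes brighter than the median (0.0574). The block added oxidative phosphorylation genes (median -0.11, adjusted p = 0.0223, 0.108 without a block, or adjusted p = 0.683 with an estimated correlation). The lists not called were glucocorticoid receptor targets (-0.0118, adjusted p = 0.275, 1 higher and 4 lower adjusted over the list alone), apoptosis regulators (0.181, 0.0517), fatty acid oxidation (-0.0318, 0.726), effector differentiation (-0.0381, 0.58), inhibitory receptors (0.159, 0.431) and migration genes (0.0603, 0.213). Markers of B cells, myeloid cells, granulocytes, NK cells, erythroid cells and stromal cells had medians between -0.0142 and 0.0692, with adjusted p between 0.182 and 0.968, and those of granulocytes and of stromal cells had negative medians but positive means. Of the genes chosen in advance, the differences were 0.76 for Cpt1a, 0.57 for Nr3c1, 0.48 for Cd8a and 0.29 for Tsc22d3. They were -0.010 for Fkbp5, -0.25 for Il7r, -0.50 for Gzmb and -3.08 for Ifng. Their adjusted p lay between 0.529 and 0.998 without a block and 0.103 and 0.995 with it.

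**Figure D3:**
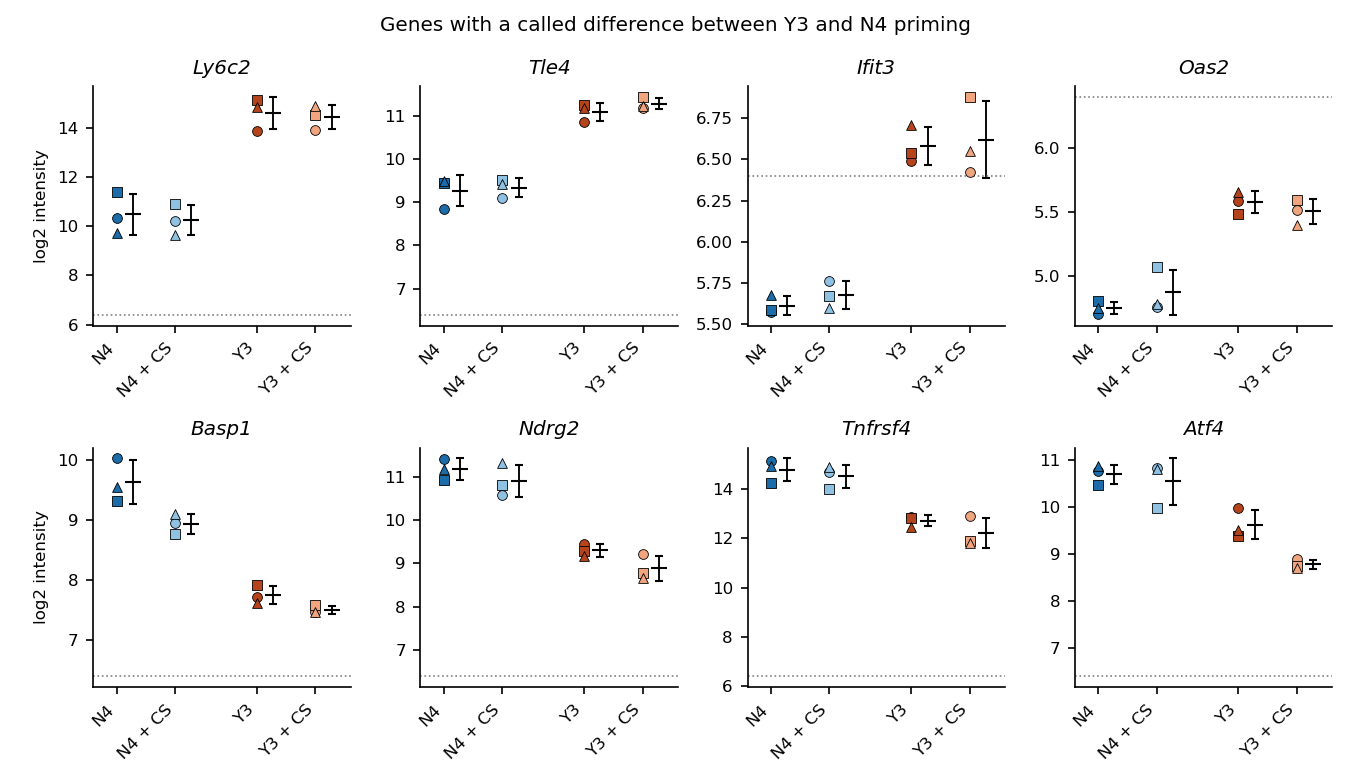
Log2 intensity of 8 genes on each array by group (CS, corticosteroid), with shapes for replicate numbers 1 (circle), 2 (square) and 3 (triangle), bars for mean ± SD (n = 3) and a dotted line at the background maximum of 6.40. Ly6c2 and Tle4 are higher after Y3 in both treatments, and Oas2 lies under the background line on all 12 arrays.

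With corticosteroid, the difference between the peptides again included Ly6c2 and Tle4, and Ccr4 and Tnfrsf4 were lower after Y3. Ly6c2 stood at 10.25 ± 0.628 log2 intensity after N4 and 14.44 ± 0.494 after Y3 (SD, n = 3), a difference of 4.19 (limma adjusted p = 0.0265), and Tle4 rose by 1.94 (0.0265). The receptor gene Gpr15 rose by 2.71 (0.0323), the adaptor gene Lax1 by 2.13 (0.0405), the lysosomal trafficking gene Lyst by 1.97 (0.0349) and F2rl1 by 1.87 (0.0265). After N4, Gpr15 (5.57) and F2rl1 (5.18) lay under the background maximum, so the sizes of their rises are uncertain. The chemokine receptor gene Ccr4 fell by 2.61 (0.0288), the transcription factor genes Batf3 by 2.48 (0.0481) and Atf3 by 2.16 (0.0486), Tnfrsf4 by 2.31 (0.0405), the mitochondrial protease gene Lonp1 by 2.23 (0.0349) and Asns by 2.16 (0.0481). All of them differed in the same direction in 3 of 3 pairs. As above, the rule that named them takes only groups that do not overlap, so this is no separate support.

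Limma without a block called 101 genes in this comparison (31 higher, 70 lower, with 4372 at an unadjusted p under 0.05), and 0 with only the 2 groups. The replicate block called 2576 (1358 higher, 1218 lower), with only the 2 groups and a block 0 (5917 unadjusted, smallest adjusted p 0.0825), with the replicate number as a random block 938 and with the block and random pairs 2372. In simulated data of this comparison, 1 of 150 calls was false without a block, 86 of 257 with the replicate block and 2 of 87 with only the 2 groups and a block. All 101 were among the 2576. Without a block, the count was 66, 6 and 38 without N4 replicate 1, 2 and 3, 15, 34 and 0 without N4_CS replicate 1, 2 and 3, 48, 0 and 15 without Y3 replicate 1, 2 and 3, and 205, 0 and 1 without Y3_CS replicate 1, 2 and 3. The count of 2576 became 1296, 1130 and 1317 without N4_CS replicate 1, 2 and 3 and 1470, 847 and 2379 without Y3_CS replicate 1, 2 and 3.

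Interferon-stimulated genes were also higher after Y3 with corticosteroid, by a median of 0.939 (camera adjusted p = 5.96e-19, or adjusted p = 0.246 with an estimated correlation), with pair medians of 0.686 to 1.44 and 34 of 37 members higher in every pair. Limma called Ifit3 (by 0.94, adjusted p = 0.0288) and Oas2 (by 0.63, 0.0462) higher over all genes, in 3 of 3 pairs each and under the background maximum on average, so with uncertain sizes. Adjusted over the list alone 14 were higher and 1 lower, and over all genes with the block 20 higher. Genes of naive and memory T cells had a median of 0.508 (camera adjusted p = 1.65e-06, pair medians 0.0227 to 1, adjusted p = 0.397 with an estimated correlation), with Ly6c2 called over all genes and 3 adjusted over the list alone. T cell identity genes had a median of 0.358 (2.87e-05, 0.35 to 0.4, adjusted p = 0.403 with an estimated correlation), with none called without a block and 7 higher with it.

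Proteostasis and stress response genes had a median of -0.928 after Y3 with corticosteroid (camera adjusted p = 3.82e-09, pair medians -0.953 to -0.471) and glycolysis genes of -0.669 (6.31e-11, -1.18 to -0.223), each with adjusted p = 0.246 with an estimated correlation. Of the former, limma called 4 lower over all genes, among them Atf4, a master regulator of the amino acid response, by 1.76 (adjusted p = 0.0323, 3 of 3 pairs), and 8 lower adjusted over the list alone. Of the glycolysis genes it called 0 over all genes and 9 lower adjusted over the list alone. With the block it called 12 over all genes, among them the triose phosphate isomerase gene Tpi1 by 2.02 (0.00898, 3 of 3 pairs). T cell activation genes had a median of -0.205 (0.0141, pair medians -0.375 to -0.2, adjusted p = 0.606 with an estimated correlation). Limma called 4 of them lower over all genes, among them the costimulatory receptor gene Tnfrsf9 by 1.84 (0.0354, 3 of 3 pairs), and 7 lower and 1 higher adjusted over the list alone. Sterol and fatty acid synthesis genes had a median of -0.684 (4.87e-06, -1.21 to 0.338), oxidative phosphorylation genes of -0.218 (7.35e-05, -0.435 to 0.0462) and proliferation genes of -0.375 (0.00875, -1.17 to 0.237), with adjusted p = 0.606, 0.606 and 0.699 with an estimated correlation.

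Without replicate 2 the calls of oxidative phosphorylation (adjusted p = 0.168) and proliferation genes (0.869) were lost, and without replicate 1 that of T cell activation genes (0.181). The block added inhibitory receptor genes (median 0.422, adjusted p = 0.0421, 0.05 without a block, or adjusted p = 0.411 with an estimated correlation). The other lists had medians of -0.0059 for glucocorticoid receptor targets (2 higher and 6 lower adjusted over the list alone), -0.0491 for fatty acid oxidation, -0.113 for effector differentiation, -0.0535 for cytokines, 0.0712 for apoptosis regulators and 0.213 for migration genes, with adjusted p between 0.0952 and 0.516. Of the migration list, 1 gene was called higher and 1 lower, the latter being Ccr4. Markers of B cells, myeloid cells, granulocytes, NK cells, CD4 T cells, erythroid cells and stromal cells had medians between -0.00945 and 0.0372, with adjusted p between 0.182 and 0.375. Of the genes chosen in advance, Cpt1a differed by 1.03, Nr3c1 by 0.64, Bcl2 by -1.33 and Gzmb by -0.80, in 3 of 3 pairs each. Their limma adjusted p was 0.21, 0.39, 0.43 and 0.651 without a block and 0.0241, 0.0471, 0.0148 and 0.0148 with it. The others differed by 0.82 (Tsc22d3), 0.66 (Cd8a), 0.48 (Il7r), 0.32 (Fkbp5) and -2.62 (Ifng, at 5.77 after Y3 and so under the background maximum). Their adjusted p lay between 0.405 and 0.843 without a block and 0.123 and 0.673 with it.

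The peptide differences with and without corticosteroid were compared by their called genes. Without a block, 6 genes were higher and 6 lower in both (0.00471 and 0.0106 expected of independent lists) and 0 opposite, and the log2 differences had a Pearson r of 0.829 across genes, which are not independent replicates. Under the replicate block 570 were higher and 432 lower in both (23.1 and 15.1 expected) and 0 opposite. Same-numbered arrays of a peptide deviated together (correlations of 0.524 to 0.815), which these expected numbers leave out, so the overlap and r are no measure of a shared effect alone.

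Whether corticosteroid acted differently after the 2 peptides was tested as an interaction. Limma called 0 genes without a block (674 at an unadjusted p under 0.05), with the replicate block (1102), in the within-peptide fit (2248, smallest adjusted p 0.854), with the replicate number as a random block (1045) and with the block and random pairs (1956). In simulated data of the interaction, the within-peptide fit found 69% of genes changed 2-fold and 92% of those changed 4-fold. The interaction values of the genes chosen in advance ran from -0.30 (Gzmb) to 0.74 (Il7r). By camera, sterol and fatty acid synthesis genes had an interaction median of -0.425 and oxidative phosphorylation genes of -0.0929, each with adjusted p = 0.0194, or adjusted p = 0.952 with an estimated correlation. The pair values ran from -0.626 to -0.284 and from -0.103 to -0.0756, and 22 of 30 sterol and fatty acid synthesis genes were lower in every pair. The sterol call was lost without replicate 1 (0.133) and with quantile normalization (0.0678), and the oxidative phosphorylation call without replicate 3 (0.363) and with quantile normalization (0.0791). The corticosteroid differences of N4-primed and Y3-primed cells had a Pearson r of 0.365 across genes (0.512 among genes brighter than the median, and 0.0789, 0.271 and 0.122 for the pairs of replicates 1, 2 and 3), and 0 genes were called in both. In the within-peptide fit 1 gene was called higher after N4 and 41 after Y3, with 0.00104 expected in both. An overlap of 0 therefore says nothing about a difference between the peptides.

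**Figure D4:**
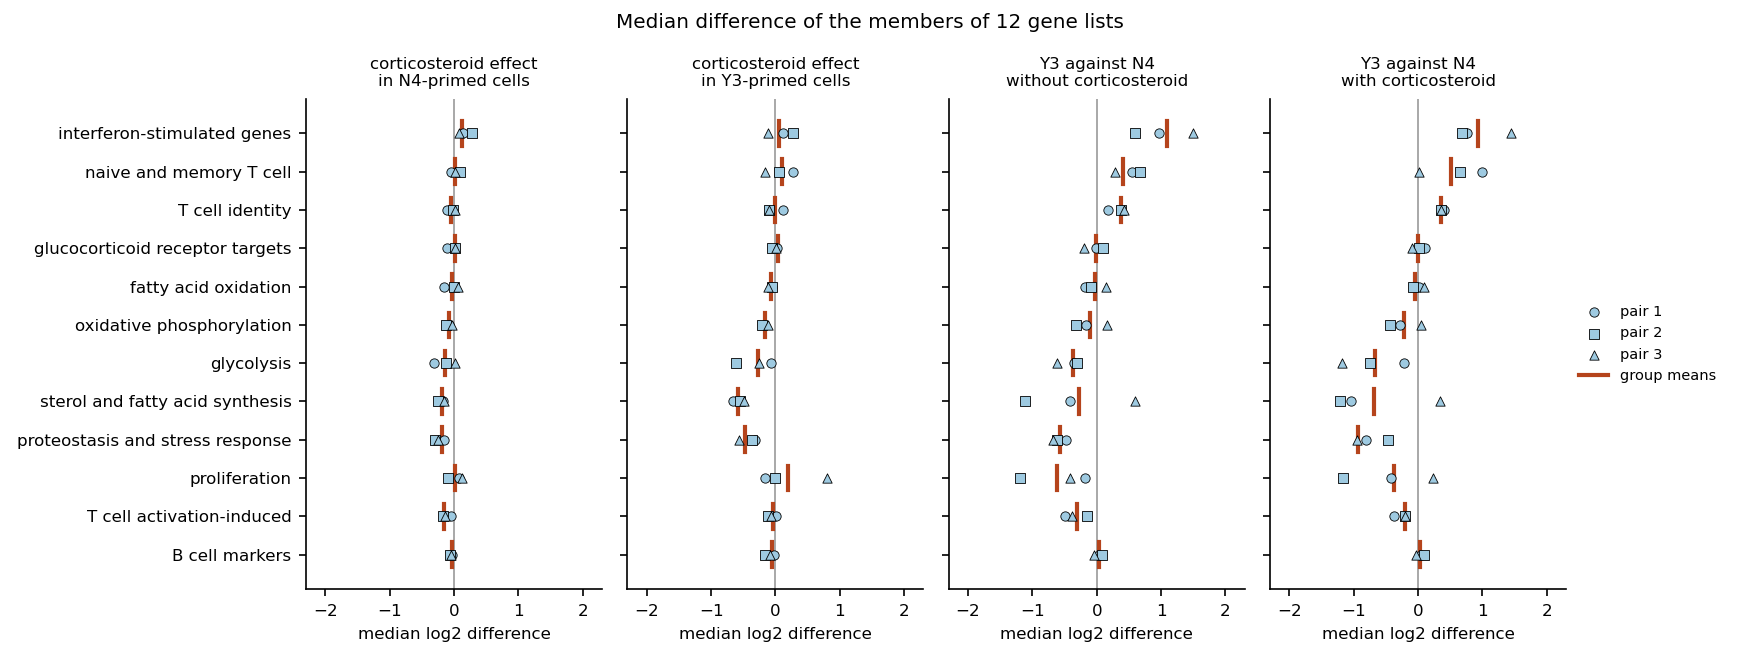
Median log2 difference over the members of 12 gene lists in the 4 comparisons, from the group means (bar) and from each same-numbered pair of arrays (symbols, pairs 1 to 3). Interferon-stimulated genes lie above 0 in every pair of both peptide comparisons, and sterol and fatty acid synthesis genes below 0 in every pair of both corticosteroid comparisons.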

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

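The patterns weighed here were chosen from the results, and the sterol pattern took the place of an earlier one on amino acid and stress genes once the list results were known. Chosen after the results were seen were the tests of other cells for the split of the arrays and for the interferon genes, the tests of proliferation and of single pairs for the sterol genes, and the regroupings of the arrays for both corticosteroid comparisons and the interaction without a block, for corticosteroid in Y3-primed cells with the replicate block and for the within-peptide interaction.

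The arrays separated by replicate number. After quantile normalization the lowest correlation of same-numbered deviations was 0.147, so a difference in signal distribution does not account for it. Between replicates 3 and 1 the largest median difference among markers of other cells was that of NK cells, -0.169, against -1.47 for the proliferation list, so the test did not show other cells as the source. Over replicates 2 and 3 alone the lowest correlation was -0.0458, so replicate 1 may stand apart from the others across peptides. A different growth state of the cultures could underlie the split, but was not tested.

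Interferon-stimulated genes were higher in Y3-primed cells without corticosteroid, with a median of 1.09. That median lay at percentile 100 among 10000 random lists of equally bright genes, so a shift that depends on brightness is unlikely. The higher of the medians of myeloid and of B cell markers was 0.035 (at most 0.0859 in a pair), and the replicate block called 2 of 30 and 1 of 21 of these markers higher and 0 lower. Single markers went both ways. Ctss of the myeloid list stood at 10.18, 10.84 and 11.81 after N4 and 10.78, 12.11 and 12.72 after Y3. H2-Ab1 of the B cell list stood at 11.91, 11.76 and 11.95 after N4 and 10.82, 10.93 and 10.98 after Y3. The medians show no general rise of such markers. A median can stay in place while single markers rise, so the test does not exclude other cells as a source. The smallest of the 3 pair medians was 0.597, so no single replicate number carried it. A stronger interferon response after Y3 could fit, but was not tested apart from transcripts.

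Sterol and fatty acid synthesis genes were lower with corticosteroid in Y3-primed cells, with a median of -0.582. Among 10000 random lists of equally bright genes that median lay at percentile 0, so a shift that depends on brightness is unlikely. The smallest fall among the 3 pairs was -0.489, so no single pair carried it. The proliferation list had a median of 0.195, but its pair medians of -0.16, -0.0014 and 0.795 go both ways, so lower proliferation stays open as a cause.

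The difference of the corticosteroid effect between the peptides stood out by its interaction test for several gene lists. By camera without a block the adjusted p was 0.0194 for oxidative phosphorylation and 0.0194 for sterol and fatty acid synthesis genes. In the within-peptide fit it was 1.02e-21 for sterol and fatty acid synthesis (median -0.425), 0.000286 for oxidative phosphorylation (-0.0929), 0.00208 for proliferation (0.142), 0.00434 for glycolysis (-0.145), 0.00438 for proteostasis (-0.116), 0.00717 for naive and memory T cell (0.0803), 0.04 for cytokine (0.0808) and 0.0451 for inhibitory receptor genes (0.0926). The pair medians crossed 0 for proliferation (-0.172 to 0.604), glycolysis (-0.503 to 0.269), proteostasis (-0.193 to 0.0623) and naive and memory T cell genes (-0.0517 to 0.471), and kept their sign for the other lists. With an estimated correlation the smallest of these adjusted p was 0.0834, for sterol and fatty acid synthesis, and none passed.

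A signal outside the genes tested came from probe sets without 1 gene symbol. In Y3 against N4 with corticosteroid 13 of 25834 passed limma without a block over 65956 probe sets, 12 higher and 1 lower, and 5 of the 13 lay above the background level. The replicate block, which gave more false calls in the self-test of the peptide comparisons, passed 1261 there. It passed 480 in Y3 against N4 without corticosteroid (0 without a block) and 2 for corticosteroid in Y3-primed cells.

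For most comparisons the ways to regroup the arrays are too few to give a share under 0.05. Without a block, as many genes or more as in the real grouping were called in 10 of 10 groupings for corticosteroid in N4-primed cells (0 genes, highest other 1), 10 of 10 in Y3-primed cells (0, 0), 1 of 10 for Y3 against N4 without corticosteroid (12, 0) and 1 of 10 with it (101, 0). With the replicate block they were 1 of 4 (1, 0), 4 of 4 (0, 0), 1 of 4 (1160, 0) and 1 of 4 (2576, 0), and with pairs within each peptide 1 of 4 for corticosteroid after N4 (1, 0), 1 of 4 after Y3 (119, 0) and 10 of 10 for the interaction (0, 0). For the interaction without a block it was 100 of 100 drawn groupings (0 genes, highest other 5966), of which 98 gave 0. Where the real grouping called 0 genes, every grouping reaches that count by definition. The shares of 10 of 10, 4 of 4 and 100 of 100 therefore carry no information. The grouping with 5966 genes sets both replicates 1 against both replicates 3, and N4 replicate 2 against Y3 replicate 2, in opposite ways in the treatments. Replicate number and the peptide difference of replicate 2 both enter it, so it points to a structure of the samples.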

How the results depend on the processing

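Chosen after the data were seen were the alternatives that leave out a replicate number, block within each peptide, use random blocks or block only the 2 groups, and all repeats under a block. The 119 gene values of the text were recomputed 3132 times, with the same direction and side of the threshold in 2466, weaker in 531, stronger in 96 and reversed in 39. Outside the averaged contrast, each was set against the planned fit without a block. That fit called 0 genes for corticosteroid after N4 and after Y3, so there the same side means not called. These counts therefore do not show how firm the calls of the blocked fits are. Of 262 recomputed list tests, 174 stayed, 87 were weaker and 1 was reversed.

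For corticosteroid after N4 the count of 0 became 1 with the replicate block, 1 with random pairs and 1 within each peptide. After Y3 it became 11 with random pairs and 119 within each peptide. Without corticosteroid the peptide count of 12 became 1160 with the replicate block, 159 with random numbers, 994 with random pairs and 297 with the 2 groups and a block. With corticosteroid 101 became 2576, 938, 2372 and 0. Only the 2 groups without a block gave 0 in both. A block takes the spread between replicate numbers out of the error, and a fit of 2 groups has fewer arrays to estimate it from. In simulated peptide comparisons without and with corticosteroid, 70 of 240 and 86 of 257 calls under the replicate block were false. Part of the rise in the peptide counts with that block may therefore be false calls.

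For other choices the cause was not tested unless fewer genes were tested. Without corticosteroid the peptide count was 23 among genes brighter than the median, 78 with array weights and 7 at 2-fold. With it the count was 54 over all probe sets, 65 with median centring, 20 with trend and robust, 1562 with array weights and 44 at 2-fold. Under the replicate block these were 2691 and 4177 with array weights and 329 and 593 at 2-fold. Within each peptide, the N4 count of 1 was 3 among genes brighter than the median, 0 over all probe sets, 2 with quantile normalization and 63 with array weights. The Y3 count of 119 was 260, 33 over all probe sets, 50 with median centring, 44 with trend and robust, 23 with array weights and 28 at 2-fold. The mean effect's 292 was 464, 178, 473 with array weights and 17 at 2-fold.

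Leaving out arrays or a replicate number gave 0 to 58 in place of 12, 0 to 205 in place of 101, and with the replicate block 25 to 1341 in place of 1160 and 79 to 2962 in place of 2576. Within each peptide it gave 0 to 1 in place of 1, 0 to 37 in place of 119 and 0 to 84 in place of 292.

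The number of called lists fell to 0 in each of the 5 contrasts with an estimated correlation, and to 0 with the block and an estimated correlation. Within each peptide with an estimated correlation it was 0 after N4, 1 after Y3 and 0 for the interaction. For corticosteroid after N4, 4 lists became 8 with the replicate block, 9 within each peptide and 3 to 7 without a replicate number. After Y3, 5 became 8 and 9. For the interaction, 2 became 4 among genes brighter than the median, 0 with quantile normalization, 8 within each peptide and 2 to 4 without a replicate number. The correlation of the corticosteroid effects, 0.365, was 0.512 among genes brighter than the median.

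Reversed values were those of small or variable differences, and the cause was not tested. With arrays or a replicate number left out, the adjusted p of the sterol list between the peptides without corticosteroid ran from 5.33e-18 to 0.612, the last with the direction turned. For corticosteroid after N4, the ranges were -0.28 to 0.26 for Bcl2, -0.035 to 0.097 for Cd8a, -0.12 to 0.49 for Cpt1a, -0.55 to 0.25 for Gzmb, -0.047 to 0.70 for Il7r and -0.32 to 0.20 for Nr3c1. After Y3 they were -0.11 to 0.48 for Cd8a, -3.26 to 0.54 for Gzmc and -0.11 to 0.10 for Nr3c1. Between the peptides without corticosteroid they were -0.32 to 0.31 for Fkbp5, -0.58 to 0.017 for Il7r and -0.0090 to 0.63 for Tsc22d3, and in the interaction -0.72 to 0.094 for Gzmb. Other choices reversed Bcl2 (-0.0053 with median centring) and Cd8a (-0.12 with quantile normalization) after N4, Nr3c1 (-0.016 with median centring, -0.012 with array weights) after Y3 and Fkbp5 between the peptides with corticosteroid (-0.069 with array weights).

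Signal over background limits the dim genes. Of 39462 genes 25246 lie at or below 6.40 log2, where a change in transcript may leave little change in intensity. Testing only the genes brighter than the median gave 260 calls in place of 119 for corticosteroid after Y3 within each peptide, with fewer genes to adjust over.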

Other observations

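Averaged over both peptides, a contrast added after the data were seen, corticosteroid changed the genes named here, taken by the rule for named genes, in all 6 same-numbered pairs. For the largest rises and falls that rule takes only genes changed the same way in every pair, so there this follows from the choice. Ifng fell by 2.45 (limma with Benjamini-Hochberg, within-peptide adjusted p = 0.00768), and the cytokine genes Lta by 1.26 (0.0173) and Xcl1 by 0.91 (0.0383). Gzma rose by 3.72 (0.0187), the steroid-induced gene Tsc22d3 by 1.33 (0.0263), Slamf6 by 1.00 (0.00768) and Il7r by 0.65 (0.0153), each in 6 of 6 pairs. The inhibitory receptor genes Pdcd1 and Cd160 rose by 1.16 (0.0406) and 0.95 (0.0189), and the cell cycle inhibitor gene Cdkn1a fell by 1.03 (0.0295), in 6 of 6 pairs. Asns fell by 1.25 (0.0153), Scd1 by 1.17 (0.0114), Gzmc by 1.15 (0.00835), the decoy receptor gene Il1r2 by 1.23 (0.0273) and Cd74 by 0.83 (0.0133), in 6 of 6 pairs. Plaur, Serpina3g and Pde2a rose by 2.35, 1.73 and 1.29 (0.0273, 0.024 and 0.0273), in 6 of 6 pairs. Plaur (6.37 after N4, 6.05 after Y3) and Serpina3g (5.97 and 6.25) lay under the background maximum of 6.40 without corticosteroid. With it, Ifng (5.77), Il1r2 (5.50) and Slc7a3 (6.38) lay under it after Y3, so the sizes of these changes are uncertain.

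That fit called 292 genes (132 higher, 160 lower, with 5192 at an unadjusted p under 0.05). With the replicate block across peptides 5 passed: Amica1 by 0.87, Npas2 by 0.96, Arl14ep by 0.83 and Pdcd4 by 0.93 higher and the amino acid transporter gene Slc7a3 by 0.88 lower (adjusted p = 0.0103, 0.0103, 0.0174, 0.02 and 0.0146, in 6 of 6 pairs each). Limma without a block called 0 (1293 unadjusted, smallest adjusted p 0.268). Leaving out an array gave 84, 9 and 1 without replicate 1, 2 and 3 of N4 or N4_CS, and 64, 11 and 41 without replicate 1, 2 and 3 of Y3 or Y3_CS. Of the 32 ways to assign the treatment within the 6 pairs, 1 reached the real count of 292 (highest other 0) and 1 that of 5 with the replicate block (highest other 0). Taken alone, such a share makes a chance assignment unlikely, but 1 of 32 is the smallest share possible. Both counts use the same 32 assignments. The contrast and the within-peptide fit were added after the data were seen, which the share does not allow for.

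Sterol and fatty acid synthesis genes had an averaged median of -0.39 (within-peptide camera adjusted p = 2.38e-28, or adjusted p = 0.0505 with an estimated correlation), with pair medians from -0.659 to -0.156. Of its 30 members 13 fell over all genes and 23 adjusted over the list alone. Proteostasis and stress response genes had a median of -0.361 (6.33e-16, or adjusted p = 0.149 with an estimated correlation, and 0.0436 with the replicate block and an estimated correlation), with 3 lower over all genes and 14 adjusted over the list alone. Cytokines and chemokines had a median of -0.0878 (0.000219, or adjusted p = 0.117 with an estimated correlation), with 3 lower over all genes, and 9 lower and 2 higher adjusted over the list alone. Of the 10 lists this fit called, oxidative phosphorylation (-0.121, 5.36e-13), glycolysis (-0.229, 1.1e-08), B cell (-0.0451, 0.00044), fatty acid oxidation (-0.0641, 0.00526) and T cell activation genes (-0.103, 0.00771) were also lower, with adjusted p = 0.155, 0.448, 0.17, 0.608 and 0.377 with an estimated correlation. Interferon-stimulated (0.0775, 0.000219, 10 higher and 1 lower adjusted over the list alone) and proliferation genes (0.0875, 0.00526) were called higher, with adjusted p = 0.608 and 0.756 with an estimated correlation. Their pairs go both ways, with medians from -0.11 to 0.278 and from -0.16 to 0.795, and 0 of 47 proliferation genes were higher in all 6 pairs.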
